A study of Mus musculus with 4 samples.

How the data were processed

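Total RNA from liver of male C57BL/6 mice was hybridised to 4 MG_U74Av2 arrays, 1 each for sham ZT2, sham ZT14, ADX ZT2 and ADX ZT14. Groups and times were taken from the sample titles. The labels give no replicate numbers and do not say whether an array stands for 1 mouse or a pool. Per the file headers, the deposited values of each array are an absolute (single-array) Affymetrix Signal per probe set, an intensity on a linear scale, with a detection call and a detection p-value. The deposited detection p-value was used only through its call (Present, Marginal or Absent). The software, its version and any scaling target are not given in the sources used here. The series value table holds the same intensities as the deposited per-array tables for all probe sets (largest difference 0). The run sheets of the arrays show 1 hybridisation day and fluidics station for all arrays, with a wash module each, so no batch could be separated from the groups.

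The deposited signals were not on a common scale, with 2% trimmed means of 64.24, 60.82, 57.01 and 55.69 in the order sham ZT2, sham ZT14, ADX ZT2 and ADX ZT14. Each array was multiplied by a factor (0.925, 0.977, 1.043 and 1.067) to a common trimmed mean. Signals below a floor of 3.91 units, the higher of the lowest Present signal (3.05) and the median Absent signal (3.91), were set to the floor, and log2 was taken. The 66 control probe sets were left out after scaling, which left 12422. Present calls covered 47.0%, 44.9%, 46.5% and 44.4% of probe sets. The control ratio of 3' to 5' signal was 1.69, 1.71, 1.89 and 1.73 for actin and 0.93, 0.95, 0.91 and 1.03 for Gapdh, in the same order. The number of arrays limits the precision. Over 4877 probe sets Present on all arrays, log2 signals of same-time arrays had Pearson r of 0.9873 (ZT2) and 0.9812 (ZT14), and those of same-operation arrays 0.9716 (sham) and 0.9742 (ADX).

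Genes were named from the platform annotation table, which gave 1 symbol for 10855 probe sets and several for 396, and did not list 1237, controls included. Of the single-gene identifiers, 10839 were found in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. No gene was named from a probe set with several symbols. Each gene was represented by its probe set with the highest mean signal (8251 genes).

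For each of 4 comparisons (ZT14 against ZT2 in sham and in ADX, ADX against sham at ZT2 and at ZT14) a probe set was called when it differed at least 2-fold and the brighter array was Present. This is a rule of size with no p-value. Where the dimmer array was not Present, the fold is the bright signal over the higher of the floor and the dim signal, a lower bound. Probe sets called in the sham pair were read in the ADX pair and the other way round. An additive model of time and operation was fitted with limma 3.58.1 (lmFit and eBayes, in R 4.3.3) to 5872 probe sets Present on at least 2 arrays, with Benjamini-Hochberg adjustment and 1 residual degree of freedom. Nothing says that the arrays of 1 time are separate animals of 1 group beyond their operation, so these p-values measure only the spread between these arrays. Other steps ran in Python 3.11.15 with NumPy 2.4.6 and pandas 2.3.3.

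Gene lists were fixed before the data were examined. They cover the core clock, glucocorticoid targets, glucose synthesis and amino acid breakdown, glycolysis and lipogenesis, cholesterol synthesis, bile acids, fatty acid oxidation, xenobiotic metabolism, heat shock and cold inducible genes, the acute phase, growth hormone and male-biased genes, cell cycle and immediate early genes, ribosomal proteins, oxidative phosphorylation, coagulation, and markers of blood and immune, endothelial, stellate, bile duct, red, hepatocyte, exocrine pancreas, adipose and skeletal muscle cells. A member was measured when Present on at least 1 array. A list with at least 5 measured members was described by its median log2 difference and its percentile among 10000 random lists of the same size, drawn with replacement within 10 classes of mean signal. A list lay outside when its percentile was under 2.5 or over 97.5. The percentile describes these arrays and is not a p-value.

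The genes named in the text follow a rule that was also fixed before the data were examined. It takes the 6 highest and 6 lowest log2 differences past 2-fold per comparison, list members past 2-fold, any measured clock or glucocorticoid target gene, the 8 genes with the largest difference of day-night differences, and the 10 smallest adjusted p of the additive fit per effect. Other named genes are said to be so where they appear, or are members of a list whose values are described.

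The steps were tested on simulated data with known differences. These were put only into probe sets Present on all 4 arrays, with the same size in both pairs. The recovery therefore does not describe calls whose dimmer array was not Present. The simulated noise was normal, with the spread of the sham day-night difference in each class of signal, which may hold real day-night differences. Detection calls were those of the real arrays. The shares below are therefore not error rates of repeated arrays. A simulated 2-fold difference lies at the threshold itself, so noise carries many of them below it. For the sham day-night comparison over 12422 probe sets, the size rule recovered 52.0% of 50 simulated 2-fold differences, 94.0% of 3-fold, and 100.0% of 4-fold and of 8-fold ones, and called 167 of 12222 unchanged probe sets (1.4%). For the time effect over 5872 probe sets, the limma fit recovered 4.0% of 2-fold, 74.0% of 3-fold, 96.0% of 4-fold and 100.0% of 8-fold differences and called 1 of 5672 unchanged ones. Of 100 random lists of 20 genes, 2 lay outside the central 95%, and of 100 lists shifted by 0.5 on the log2 scale 99 lay above it.

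Alternatives were quantile normalization, scaling to the median of probe sets Present on all arrays, no detection filter, Present on both or on all arrays, a floor of 1 unit or a doubled floor, thresholds of 3-fold and 1.5-fold, the series value table, a variance trend in eBayes, a model without the other factor, averaging all probe sets of a gene, and other probe sets of a gene. A floor at the 95th percentile of Absent signals (23.9 units) and signals as deposited were added after seeing the data.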

Results

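Messenger RNA was measured in the liver of male C57BL/6 mice on 4 Affymetrix MG_U74Av2 GeneChips, 1 array per group. The groups crossed an operation with a time of day. Mice were either sham-operated or had lost both adrenal glands (ADX, bilateral adrenalectomy, with saline to drink), which removes the main source of circulating glucocorticoids. Liver was taken at zeitgeber time (ZT) 2 or ZT14, where ZT counts the hours from lights on. The labels do not say how many animals stand behind an array. The series title speaks of a pair of circadian oscillatory mechanisms in the liver, and the design asks which ZT14 against ZT2 differences, called day-night differences here, are seen with and without adrenal glands. Probe sets called Present numbered 5865 on the sham ZT2 array, 5611 on sham ZT14, 5810 on ADX ZT2 and 5543 on ADX ZT14. Because each group had 1 array, no difference between arrays has a replicate check. A probe set was called different by size alone, when it differed at least 2-fold and was Present on the brighter array, and to pass 2-fold means to meet both conditions. Folds against an array without a Present call are written as at least that size, against a floor of 3.91 signal units or the dim signal if higher, and they shrink with a higher floor. Across probe sets Present on both arrays of a comparison, the log2 difference had a robust SD of 0.35 in the sham day-night pair, 0.33 in the ADX pair, 0.25 between operations at ZT2 and 0.31 at ZT14.

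In the sham pair, genes of the circadian clock and its output differed between the times of day. The signal of Dbp, a clock output transcription factor, was 98.2 at ZT14 and not Present at ZT2, at least 25.1-fold higher. Usp2, a rhythmically expressed ubiquitin protease, was at least 18.5-fold higher at ZT14, and its other probe set also passed 2-fold. Noct, which encodes nocturnin, was 15.6-fold higher. Per2, a core repressor of the clock, was 6.15-fold higher, with Bhlhe40 at 6.35-fold, Tef at 5.95-fold and Nr1d2 at 2.73-fold. Arntl, which encodes the clock activator BMAL1, was 13.7-fold lower at ZT14, and Nfil3, a repressor that opposes Dbp, was 2.73-fold lower. Of 17 measured members of the core clock list, 7 were at least 2-fold higher at ZT14, 2 were lower and 8 passed neither way. The list's median log2 difference was 0.46, above the central 95% of random lists matched on signal. Its members went both ways, and over the 10 members Present on all 4 arrays the median was -0.07, inside the random range. Raising the floor to 23.9 units took the log2 differences of Dbp and Arntl from 4.65 and -3.78 to 2.04 and -1.65, left Per2 barely past 2-fold and ended the call of Wee1, a cell cycle kinase in the list. Of the 3 probe sets of Noct, 1 showed 0.00 in this pair, while the other probe set of Nfil3 gave -0.99, under 2-fold.

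Beyond the clock genes, the metal-binding metallothioneins Mt2 and Mt1 were 8.0-fold and 6.41-fold higher at ZT14 in the sham pair, and the haem synthesis enzyme Alas1 was 3.28-fold higher. Among heat shock and cold inducible genes, 4 of 23 measured members were at least 2-fold higher and none was lower, and the median of 0.30 lay above the random range. They were Hspa1b at 5.64-fold, Hspa1a at 3.26-fold, and Hmox1 and Creld2, both at 3.06-fold. Hspa1a and Hspa1b are near-identical genes, and their probe sets are not told apart here. Of 30 measured glucocorticoid targets, 6 were higher at ZT14 and 3 were lower, with a median of 0.20 at percentile 99.8. The higher ones were Mt1, Mt2, Lpin1, a phosphatidate phosphatase, at 5.41-fold, St3gal5, a ganglioside synthase, at 5.1-fold, Fkbp5, a co-chaperone of the glucocorticoid receptor, at 3.51-fold and Dusp1 at 3.0-fold. The lower ones were Igfbp1, an insulin-repressed binding protein of insulin-like growth factors, at 22.7-fold, Pdk4 at 2.5-fold and G6pc, the last enzyme of glucose output, at 2.26-fold. Averaging all probe sets of each gene brought this list's median to 0.12, inside the random range. The fatty acid elongase Elovl3 was at least 28.6-fold lower at ZT14, the immediate early gene Egr1 at least 7.17-fold lower, and the tubulin probe sets named Tubb2a and Tubb3, which belong to a family of similar sequences, were 6.48-fold and 6.37-fold lower. With the floor at 23.9 units Hspa1a (log2 0.59) and Pdk4 (-0.15) no longer passed 2-fold, and Elovl3 and Egr1 passed at -2.23 and -1.68.

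Genes of lipid metabolism went both ways between the times in the sham pair. Of 14 glycolysis and lipogenesis genes, Elovl3 and Elovl5 (2.51-fold) were at least 2-fold lower, while Elovl6 (2.05-fold, and log2 0.93 by its other probe set) and Thrsp (2.91-fold) were higher. The list's median was -0.32, at percentile 0.1, and -0.11 and inside the random range when all probe sets of a gene were averaged. Of 16 cholesterol synthesis genes, only Hmgcs1 passed 2-fold (2.09-fold lower), with a median of -0.26 at percentile 0.4. For the bile acid genes, Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 2.39-fold higher and Cyp8b1 2.2-fold lower, and the list's median of 0.05 lay inside the random range, as did the median of -0.06 of 21 fatty acid oxidation genes. In all, 367 probe sets passed 2-fold in the sham pair, 211 higher and 156 lower at ZT14. Quantile normalization turned the split to 161 higher and 193 lower, and signals as deposited gave 173 and 198. Of the 367 probe sets, 50.4% were not Present on the dimmer array, and 142 passed when the floor was raised to 23.9 signal units.

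**Figure D1:**
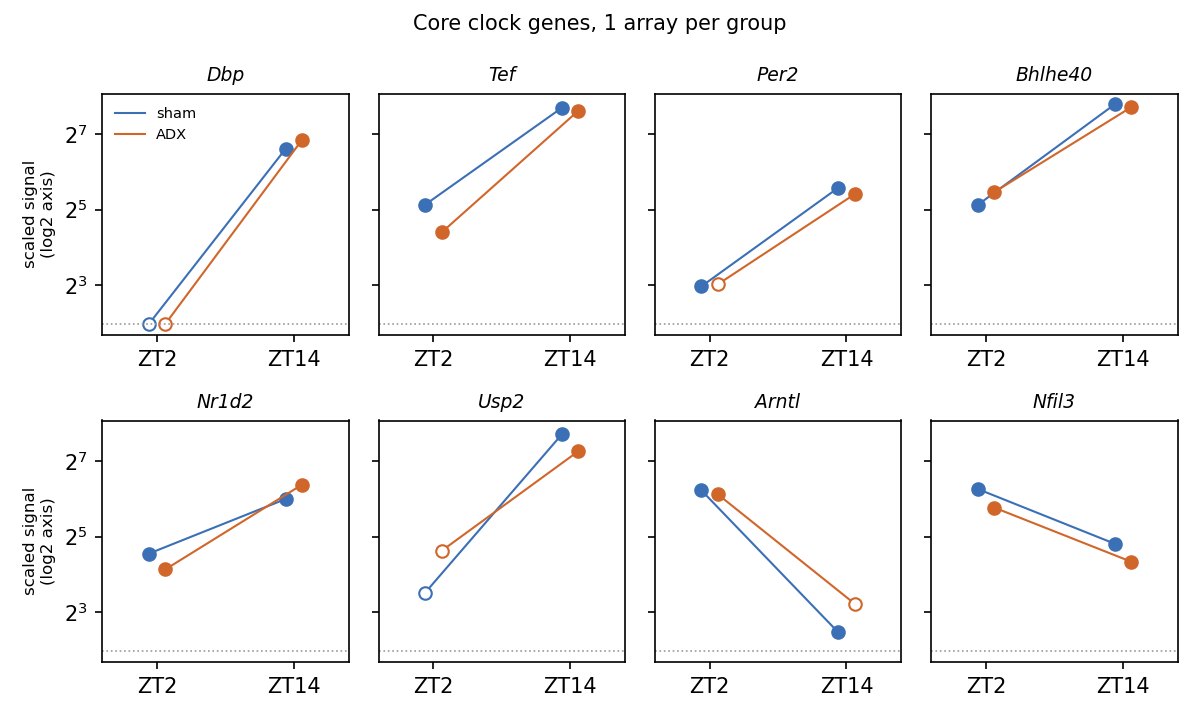
Scaled signal (log2 axis) of 8 core clock genes at ZT2 and ZT14 in the sham (blue) and ADX (orange) arrays. Filled points were called Present, open points were not, the dotted line is the floor of 3.91 units, and each point is 1 array. Dbp, Tef, Per2, Bhlhe40, Nr1d2 and Usp2 were higher at ZT14 in both pairs, and Arntl and Nfil3 lower.

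Without adrenal glands, the clock genes again differed between the times of day. In the ADX pair Dbp was at least 29.6-fold higher at ZT14, Noct 16.7-fold, Tef 9.41-fold, Nr1d2 4.75-fold and Bhlhe40 4.76-fold. The other probe sets of Noct gave log2 differences of 2.66 and -0.24. Per2 was at least 5.22-fold and Usp2 at least 6.26-fold higher, Arntl at least 7.5-fold lower and Nfil3 2.71-fold lower. Of 17 core clock members, 7 were higher, 3 lower (Arntl, Nfil3 and Per3) and 7 passed neither way. The median was 0.53, above the random range, and 0.11 and inside the random range over members Present on all 4 arrays. Mt1 was 17.1-fold and Mt2 6.49-fold higher, Alas1 3.35-fold higher, Elovl3 at least 13.5-fold lower, and the water channel Aqp8 4.97-fold lower. Avpr1a, a vasopressin receptor, was at least 9.43-fold lower, but its other probe set gave a log2 difference of -0.97, under 2-fold. With the floor at 23.9 units Per2 (0.83), Wee1 (0.00) and Per3 (0.00) no longer passed in this pair, and Dbp, Arntl, Elovl3 and Avpr1a passed at 2.28, -1.55, -2.10 and -1.08.

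Of 16 cholesterol synthesis genes, all had a lower signal at ZT14 in the ADX pair, and 5 passed 2-fold. These were Hsd17b7 (at least 2.68-fold), Hmgcs1 (2.36-fold), Idi1 (2.24-fold), Fdps (2.15-fold) and Nsdhl (2.15-fold). Hsd17b7 did not pass with the floor at 23.9 units (0.00), nor did the other probe set of Fdps (-0.81). The list's median of -0.55 lay at percentile 0.0, and below the random range under all 7 alternatives for lists. Of 30 glucocorticoid targets, 5 were higher (Mt1, Mt2, Pck1, Serpina6 and St3gal5) and 3 lower (Igfbp1, Bcl6 and Klf9, the last at -0.28 by its other probe set), with a median of 0.19 at percentile 99.6, and 0.11 and inside the random range when all probe sets of a gene were averaged. Pck1, the first committed enzyme of glucose synthesis, was 3.61-fold higher at ZT14, and Serpina6, the corticosteroid-binding globulin, 3.77-fold. The 19 genes of glucose synthesis and amino acid breakdown had a median of 0.11 at percentile 98.3 (96.9, inside the random range, when all probe sets of a gene were averaged), and the 21 fatty acid oxidation genes 0.11 at percentile 97.8. In the heat shock list only Hspa1b passed 2-fold (3.58-fold higher), with a median of 0.19 at percentile 99.8. In all, 327 probe sets passed 2-fold, 177 higher and 150 lower, against 147 and 201 under quantile normalization. With the floor at 23.9 units, 120 passed.

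The sham and ADX pairs share no array, so their overlap owes nothing to a common control. Higher in both pairs were 41 probe sets, where independent lists drawn from the 6583 probe sets Present on at least 1 array would share 5.7, and lower in both were 38, where 3.6 would be shared. These 79 made up 21.5% of the 367 called in the sham pair. Of the 367, 275 (74.9%) had the same sign in the ADX pair and 52.0% differed there by less than 1.5-fold. With the floor at 23.9 units, 38.7% of the sham calls passed in the ADX pair. Read the other way, the 79 made up 24.2% of the 327 called in the ADX pair. Among probe sets with a mean signal of 100 or more, 33 of 67 sham calls (49.3%) and 33 of 62 ADX calls (53.2%) passed in the other pair, and 91.0% of those sham calls had the same sign, with 26.9% under 1.5-fold. Across the 4877 probe sets Present on all 4 arrays, which are not independent replicates, the day-night differences of the pairs had a Pearson r of 0.47. Past 2-fold in opposite directions were 4 probe sets (Bmp6, Eif2ak2, Sspo and Zfp292, named because they are so few), all with signals near 20 or lower. Cyp2b9 was 7.99-fold higher at ZT14 in the ADX pair and not Present in sham. Kap, Dync1i1 and Shbg also stood apart between the pairs, but each rests on arrays without a Present call, so the size of its difference depends on dim signals or on the floor. Kap (0.74) and Dync1i1 (0.88) did not pass in the ADX pair with the floor at 23.9 units, and Shbg (0.00) did not pass in sham. No test of these differences is possible with 1 array per group.

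**Figure D2:**
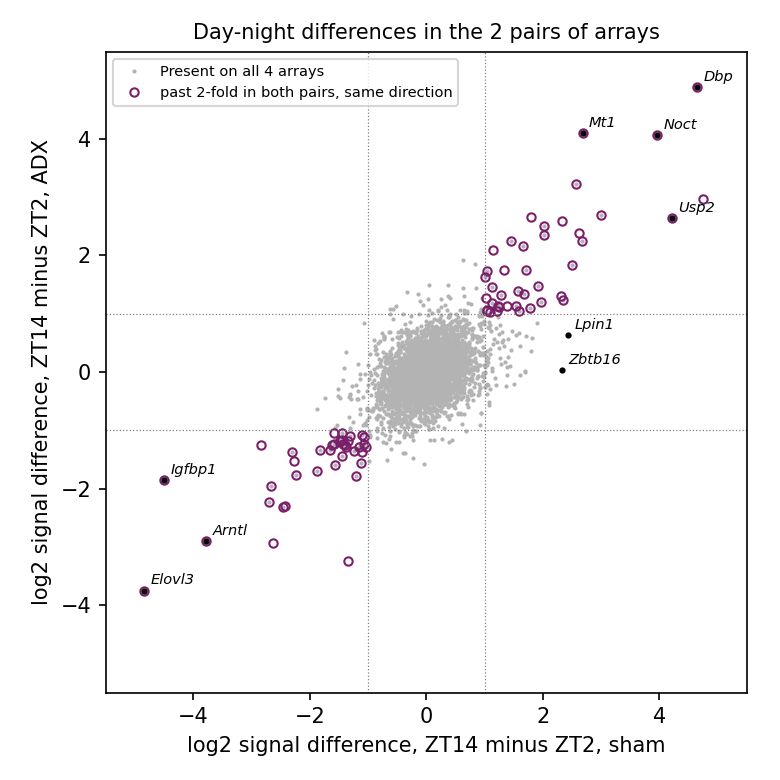
Log2 signal difference, ZT14 minus ZT2, in the sham pair (horizontal axis) against the ADX pair (vertical axis). Grey points are the 4877 probe sets Present on all 4 arrays, purple rings the 79 past 2-fold in both pairs in the same direction, black points named genes, and dotted lines mark 2-fold. Dbp, Noct and Usp2 lie at the upper right, Arntl, Elovl3 and Igfbp1 at the lower left, and Lpin1 and Zbtb16 were 5.41-fold and 5.04-fold higher at ZT14 in sham only past the 2-fold line.

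Taking both operations as samples of each time, an additive limma fit of time and operation tested the day-night effect over 5872 probe sets. Dbp was higher at ZT14 by a log2 difference of 4.77 (SE 0.17, Benjamini-Hochberg adjusted p = 0.0396) and Noct by 4.01 (SE 0.16, adjusted p = 0.0396), each in both pairs. Both ZT2 signals of Dbp were set to the floor, so its size and SE depend on that floor (6.60 with a floor of 1 unit). No other probe set passed, those of Noct included, while 773 had an unadjusted p under 0.05. Among the next were Mt2, Per2, Aqp8, Denn2b and Slc5a6, each at an adjusted p of 0.0921 and in the same direction in both pairs. Denn2b and Slc5a6 passed 2-fold in neither pair when the floor was raised to 23.9 units. The fit has 1 residual degree of freedom, which also holds any difference between the pairs. It called 0 probe sets with no detection filter, a doubled floor or a floor of 23.9 units, Noct alone over probe sets Present on all 4 arrays, Dbp alone with a floor of 1 unit, 154 with a variance trend on signal (77 in each direction), and 11 without a term for operation.

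At ZT2, ADX and sham livers differed in genes of glucose output and in glucocorticoid targets. Igfbp1 was 4.37-fold lower in ADX and Pck1 2.36-fold lower. The enzyme gene G6pc was 1.98-fold lower, short of 2-fold. Of 19 measured genes of glucose synthesis and amino acid breakdown, 18 had a lower signal in ADX and Pck1 alone passed 2-fold. Ass1, of the same list, was 2.76-fold lower but did not count, as its sham array had a Marginal call. The list's median was -0.24 at percentile 0.0. Tat, the first enzyme of tyrosine breakdown, had a log2 difference of -0.49 and Tdo2, which starts tryptophan breakdown, -0.25. Of 30 glucocorticoid targets, Igfbp1, Lpin1 (2.1-fold) and Pck1 were lower and Cdkn1a, an inhibitor of the cell cycle, was 2.16-fold higher (log2 0.52 with the floor at 23.9 units, under 2-fold). That list's median was -0.18 at percentile 0.0, and both medians stayed below the random range under all 7 alternatives for lists. Pck1, G6pc, Tat and Tdo2 stand in both lists. The clock list had no member called (Usp2 was 2.16-fold higher but not Present on either array) and a median of -0.11 inside the random range, but with a floor of 1 unit the median was -0.26, and over the 10 members Present on all 4 arrays it was -0.34, both below that range.

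Cyp4a14, a fatty acid hydroxylase induced through PPARα, was 2.99-fold lower in ADX at ZT2, Egr1 2.23-fold lower, and Hmox1, the haem oxygenase, 2.04-fold higher. The 19 acute phase genes had a median of 0.13 at percentile 99.8 with no member past 2-fold. Most of them code for plasma proteins of inflammation, and the metallothioneins Mt1 and Mt2 are also among them. The medians were 0.13 (percentile 99.5) for heat shock genes, -0.09 (percentile 1.2) for 39 genes of xenobiotic metabolism, -0.14 (percentile 0.9) for glycolysis and lipogenesis, and -0.20 (percentile 1.0) for 17 cell cycle and immediate early genes. The lipogenesis median became -0.04 and inside the random range when all probe sets of a gene were averaged, and the cell cycle median became 0.00 and inside with the floor at 23.9 units. In all, 160 probe sets passed 2-fold, 108 higher and 52 lower in ADX. The split was 68 higher and 80 lower under quantile normalization, and 69 and 90 with signals as deposited. Of the 160, 75.0% were not Present on the dimmer array, only 9 had a mean signal of 100 or more, and 20 passed with the floor at 23.9 units. Lyst, Epha8, Hoxb1, Zfp105 and Plcg1, all higher in ADX past 2-fold, had signals of at most 21.6 on all 4 arrays, and no theme is drawn from them.

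At ZT14, several glucocorticoid targets were lower in ADX. Lpin1 had a signal of 324.0 in sham and 44.3 in ADX, 7.31-fold lower. Zbtb16, a zinc finger transcription factor outside the fixed lists, was 7.87-fold lower, St3gal5 2.71-fold and Fkbp5 2.66-fold. Of 30 measured glucocorticoid targets, these 3 list members (Lpin1, St3gal5 and Fkbp5) were lower, Mt1 (2.81-fold) and Serpina6 (2.08-fold) were higher, and 25 passed neither way. The other probe set of Serpina6 gave a log2 difference of 0.45, under 2-fold. The list's median of -0.05 lay inside the random range. At this time Pck1, Tat and G6pc had log2 differences of -0.22, -0.07 and 0.33, all under 2-fold. Slc37a4, the transporter that feeds G6pc its substrate, was 2.0-fold lower. Csad, an enzyme of taurine synthesis, had signals of 628.7, 611.2 and 579.1 on 3 arrays and 195.1 on the ADX ZT14 array, 3.13-fold lower than in sham.

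Cyp2b9, a cytochrome P450 gene, was not Present in sham and had a signal of 238.4 in ADX at ZT14, at least 38.1-fold higher. Its signal was 29.8 in ADX at ZT2, at least 3.32-fold above sham. Kap, known as an androgen-regulated kidney protein, was Present only on the ADX ZT14 array, at least 9.94-fold higher, and Cyp2b13 likewise at least 4.23-fold. With the floor at 23.9 units Cyp2b9 passed at ZT14 (log2 3.32) and not at ZT2 (0.32), and Kap (0.74) and Cyp2b13 (0.00) did not pass. Of 16 cholesterol synthesis genes, 13 had a lower signal in ADX at ZT14 and Hsd17b7 passed 2-fold (at least 2.55-fold lower). The list's median was -0.33 at percentile 0.0. The clock list's median was -0.08, inside the random range, with Per3 (at least 2.03-fold lower) the only member past 2-fold. Neither Hsd17b7 nor Per3 passed with the floor at 23.9 units. In all, 244 probe sets passed 2-fold, 147 higher and 97 lower in ADX, against 118 and 120 under quantile normalization and 106 and 137 with signals as deposited. Of the 244, 74.6% were not Present on the dimmer array, 17 had a mean signal of 100 or more, and 46 passed with the floor at 23.9 units.

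**Figure D3:**
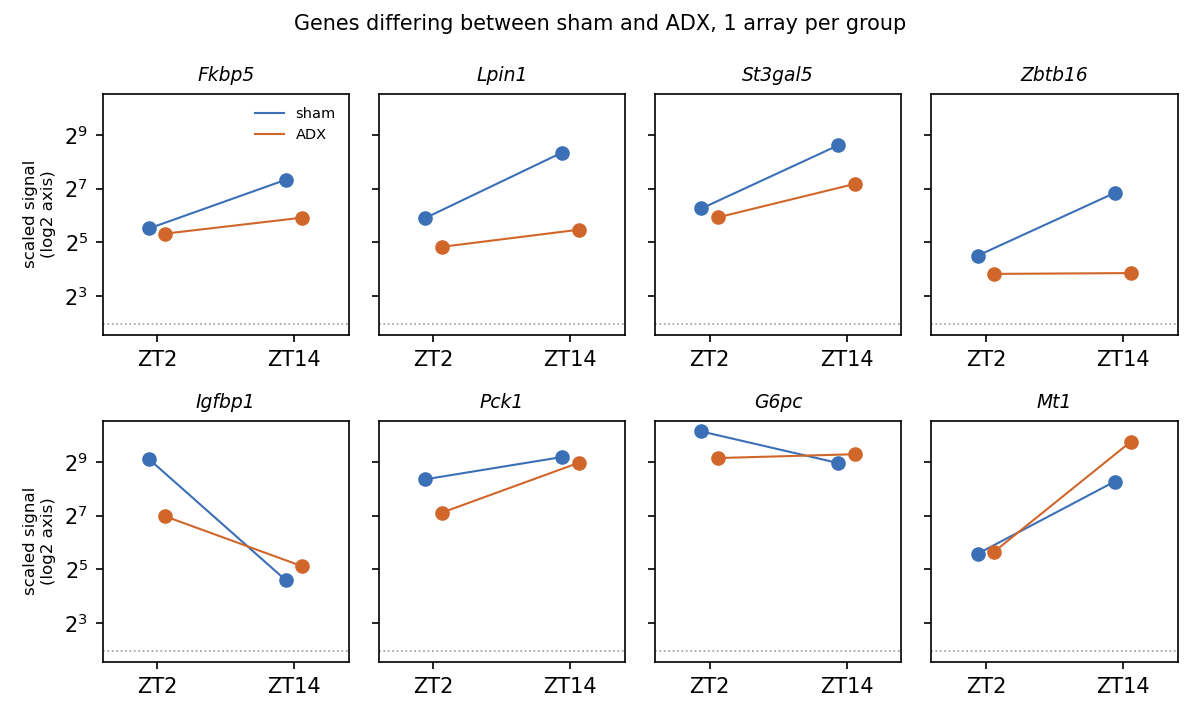
Scaled signal (log2 axis) at ZT2 and ZT14 in the sham (blue) and ADX (orange) arrays for 8 genes past 2-fold in at least 1 comparison. All points were called Present, the dotted line is the floor of 3.91 units, and each point is 1 array. At ZT14 Lpin1 was 7.31-fold and Zbtb16 7.87-fold lower in ADX than in sham, and at ZT2 Igfbp1 was 4.37-fold and Pck1 2.36-fold lower.

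Over both times, the additive limma fit called 0 of 5872 probe sets for the operation at an adjusted p of 0.05, and 329 had an unadjusted p under 0.05. The smallest adjusted p was 0.0603. It belonged to the probe set described in the files as adipsin, a serine protease made mainly by fat tissue, with a log2 difference of 4.75 (SE 0.17). It was not Present in sham, at signals of 4.4 and 4.2, and Present in ADX, at 132.7 at ZT2 and 101.3 at ZT14, at least 29.9-fold and at least 24.1-fold higher. The size depends on the floor, with a log2 difference of 3.89 when it was doubled and 2.28 at 23.9 units. Under quantile normalization, median scaling, a variance trend or no term for time, this probe set passed, at adjusted p values of 0.0341, 0.0461, 0.000898 and 0.0162. Over the 8 alternatives that tested it, its adjusted p ran from 0.000898 to 0.575. By size, 13 probe sets were higher in ADX at both times, where independent lists drawn from probe sets Present on at least 1 array would share 2.4, and 3 were lower, where 0.8 would be shared. The 3, named because they are so few, were Lpin1, Myc and a dimmer probe set of Peg3. The brightest probe set of Peg3 went the other way, at 0.48 and 1.33, so no direction is given for this gene. Myc had signals under 20 on all 4 arrays and did not pass with the floor at 23.9 units. The same holds at both times for Ryr3, Igkv8-19, Thbs2 and Mmp12 among the 13 higher ones. It also holds for probe sets of Ppfibp2 and Otulinl and for a probe set without a symbol, picked for their dim signals. Wwp2, with signals of at most 25.6, could not pass that floor either, and Cyp2b9 did not pass at ZT2 (log2 0.32). The rest, Rnf145, Cyp26a1, the adipsin probe set and another probe set without a symbol, were brighter. Much of the overlap of higher calls thus rests on dim signals. Neither overlap was recomputed with another floor or scaling, and the balance of higher and lower calls rests on the scaling.

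Markers of other cell types in the liver piece were read beside these groups. Adipose markers, of which 5 were measured, had medians of 0.12 at ZT2 and -0.04 at ZT14 in ADX against sham, both inside the random range. Lpl, the lipoprotein lipase, was 2.09-fold higher in ADX at ZT14, and Fabp4 had a log2 difference of -0.95. Of 21 blood and immune cell markers, the class II antigen gene H2-Ab1 (at least 2.01-fold) and the B cell gene Ms4a1 (at least 2.32-fold) were higher in ADX at ZT14, and the median of 0.22 lay at percentile 98.7. Ms4a1 did not pass with the floor at 23.9 units (log2 0.64). Other B cell and antibody genes of the list went both ways, with Ighm at 0.75, Cd79a at -0.62 and Jchain at -0.65. Red cell markers, with 8 measured, had a median of 0.45 (percentile 99.6) at ZT14 against ZT2 in ADX and -0.24 (percentile 1.5) in ADX against sham at ZT2. Hba-a1, an alpha globin gene, was 2.05-fold higher in ADX than in sham at ZT14. Endothelial markers had a median of -0.30 (percentile 1.4) between the times in sham, with none of 11 past 2-fold. Under a floor of 23.9 units the red cell medians were 0.20 and -0.09 and the endothelial median -0.12, all inside the random range. Over 84 list comparisons, 24 lay outside the central 95% of random lists. The 84 are not independent, since the comparisons share arrays and the lists share genes, so no chance number is given for them.

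**Figure D4:**
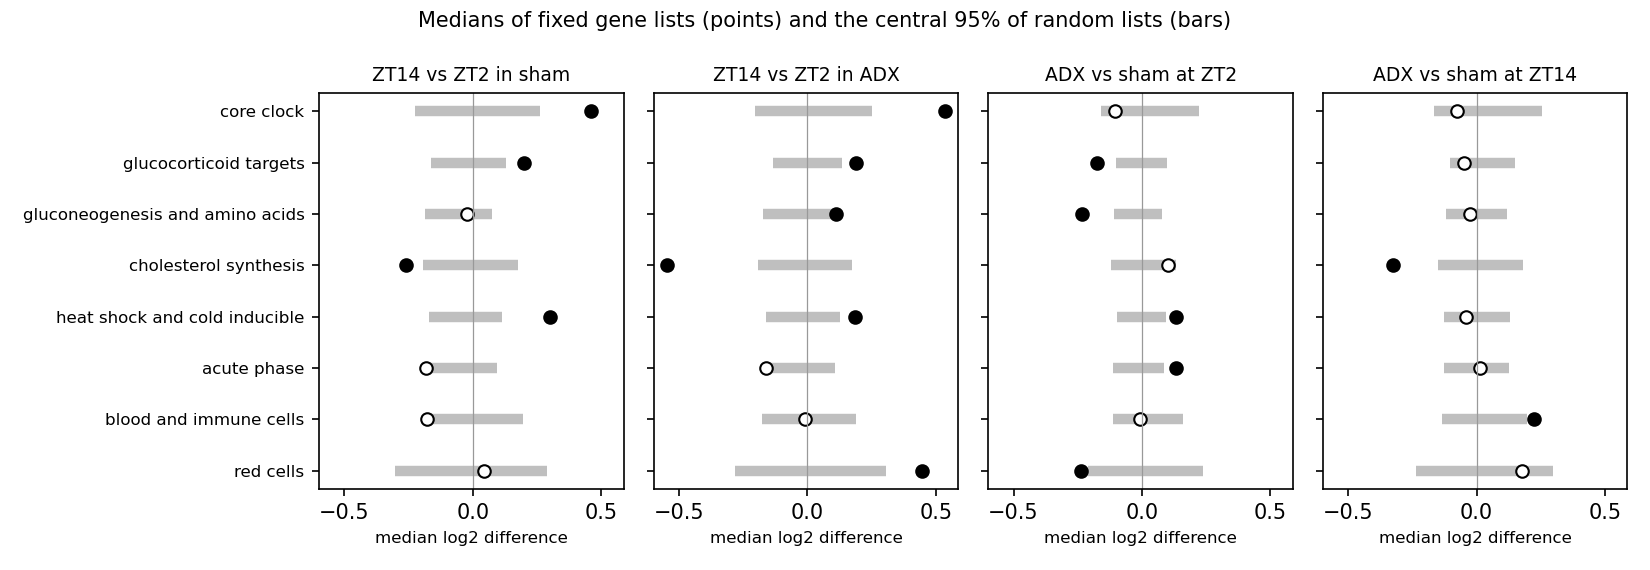
Median log2 difference (horizontal axis) of 8 fixed gene lists in the 4 comparisons of arrays. Points are list medians, filled where outside the central 95% of 10000 random lists matched on signal, which the grey bars show. Cholesterol synthesis lay at -0.55 between the times in ADX, and glucose synthesis and amino acid genes at -0.24 in ADX against sham at ZT2.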

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

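The first results below stand out because a probe set passed 2-fold in opposite directions in the sham and ADX pairs, or at ZT2 and ZT14. The differences between the pairs were not tested, since each group had 1 array. The test on sex-biased genes was chosen after the result was seen.

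For Bmp6, which encodes a bone morphogenetic protein, the day-night difference in ADX minus that in sham was -2.93. Its signals were 3.1, 14.2, 8.2 and 3.3 in the order sham ZT2, sham ZT14, ADX ZT2 and ADX ZT14. For Eif2ak2, the interferon-induced kinase PKR, it was 2.89, with signals of 9.6, 2.4, 3.5 and 11.7. For Sspo it was 2.33, and for Zfp292 it was -2.56. The operation differences of Bmp6 and Eif2ak2 were opposite at the times of day as well, by the same -2.93 and 2.89 (ZT14 minus ZT2), and that of Itgav by -2.25. All of these signals were 20.4 or lower, and each of these probe sets fell short of a Present call on at least 1 array. Their sizes therefore rest on dim signals, and for Bmp6 and Eif2ak2 also on the floor.

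Lpin1, Zbtb16, Fkbp5 and St3gal5 were higher at ZT14 in sham than in ADX, with a median log2 difference of -2.16 (ADX minus sham). Scaling between arrays is argued against as the cause, since the median was -2.19 under median scaling and -2.20 under quantile normalization. A fault of single probe sets stays open, because 0 other probe sets of these genes were Present on the sham ZT14 array. Fkbp5, Lpin1 and St3gal5 stand in the glucocorticoid target list, so a response to adrenal steroids in the sham animals at ZT14 may be behind the pattern. With 1 array per group it was not tested against variation between animals. The 4 genes were picked for this difference, and the list as a whole did not follow them. Its median at ZT14 was -0.05 (percentile 14.0), inside the random range, and Mt1 (log2 1.49) and Serpina6 (1.06) were higher in ADX.

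Few day-night differences of the sham pair stood in the ADX pair, with 21.5% kept at 2-fold (38.7% with the floor at 23.9 units), though 74.9% had the same sign there. Of sham calls with a mean signal of 100 or more, 49.3% were kept (33 of 67, exact binomial 95% interval 36.8% to 61.8%), against 15.3% of dimmer ones. The interval treats probe sets of the same arrays as independent, which they are not, and holds no variation between animals. Noise of dim probe sets may be behind part of the loss. Whether it is behind all of it stays open. The bounds written beforehand, over 80% kept among bright probe sets if it were and under 50% if not, were assumed. In simulated data the size rule recovered 52.0% of 2-fold differences in probe sets Present on all arrays. The noise of that simulation was the spread of the sham pair itself, which may hold real differences. Under it, calls near the threshold are lost even where nothing changed, and the lower bound decides nothing. Read the other way, 24.2% of ADX calls passed in sham, and 53.2% of those with a mean signal of 100 or more. The same kept probe sets are counted in both readings, so the low share is not by itself a loss in ADX. Probe sets picked for a large difference in a pair fall back in the other without a change of rhythm. How much this makes up, and whether particular genes lose rhythm in ADX, was not tested.

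Cyp2b9, Kap, Cyp2b13, Gpx3 and Hao2 were high on the ADX ZT14 array. Gpx3 and Hao2 were picked after their values were seen, with at least 3.87-fold and 3.25-fold higher signals than in sham at ZT14. With the floor at 23.9 units Cyp2b9 alone of the 5 passed 2-fold (log2 3.32), with Gpx3 at 0.75, Kap at 0.74 and Cyp2b13 and Hao2 at 0.00. A sample of the wrong sex is argued against, since 0 of 4 arrays had sex-linked calls that did not match the label. Kidney tissue stays open. Of 25 kidney markers on the array 1, Klk1, was Present on the ADX ZT14 array alone, at 18.7 against 14.9 in sham, the abundant Umod was not Present at 4.2, and the 5 measured markers had a median of 0.29 (percentile 72.4), too few to decide. A general shift of sex-biased liver genes towards the female side also stays open. Female-biased genes had a median of 0.34 (8 measured, percentile 98.9, 4 of them also in the fixed lists) in ADX against sham at ZT14. Male-biased genes had a median of -0.28 (11 measured, percentile 0.2). Without the genes picked by the naming rule, the 5 female-biased genes left lay at percentile 90.3, and the 10 male-biased genes left at percentile 0.0. Elovl3, the male-biased gene left out, had a log2 difference of 0.955. It was Present on neither ZT14 array (signals of 2.7 in sham and 7.6 in ADX), so this value rests on the floor. The fixed growth hormone list, examined earlier, shares 8 of the male-biased genes, so the repeat is not a reading of unseen genes. That fixed list had a median of 0.01 (percentile 49.2) in this comparison. It mixes male-biased genes with others, among them the female-biased Cyp2b9 and Cyp2b13, so its median cannot decide for or against such a shift.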

How the results depend on the processing

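The floor at the 95th percentile of Absent signals and the signals as deposited were chosen after seeing the data; all other alternatives were planned. Counts are given in the order sham day-night, ADX day-night, ADX against sham at ZT2, the same at ZT14, and sham calls kept in ADX, where the reported values were 367, 327, 160, 244 and 79. No detection filter gave 1120, 1180, 799, 1156 and 193, as more probe sets could pass. Requiring Present on both arrays gave 182, 144, 40, 62 and 52, since fewer could. A 3-fold threshold gave 86, 69, 25, 40 and 26, and a 1.5-fold threshold 1110, 1033, 646, 864 and 276, by construction. A doubled floor left 77 at ZT2 and 135 at ZT14 between operations. The floor of 23.9 units left 142, 120, 20 and 46 in the 4 comparisons and 55 kept. Signal over background therefore limits these counts. Quantile normalization, median scaling, a floor of 1 unit and signals as deposited kept all 5 counts within 1.5 times. The series value table gave identical counts, as its values are the same. Without scaling, the median probe set Present on all arrays shifted by -0.172 at ZT2 and -0.113 at ZT14 in ADX against sham. The arrays had been scaled because their trimmed means differed. Quantile normalization put fewer probe sets on the higher side in every comparison, 45.5% against 57.5% in sham day-night, 42.2% against 54.1% in ADX, 45.9% against 67.5% at ZT2 and 49.6% against 60.2% at ZT14, so the balance of higher and lower calls rests on the scaling.

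In the additive fit, time called 2 probe sets as reported, 0 with no detection filter, with a doubled floor or with the floor of 23.9 units, 1 with Present on all 4 arrays (Noct) or a floor of 1 unit (Dbp), 154 with a variance trend, and 11 without a term for operation. Operation called 0 as reported and 1, the adipsin probe set, under quantile normalization, median scaling, a variance trend and no term for time. With other settings its adjusted p was 0.575 (no detection filter), 0.0836 (floor of 1 unit), 0.495 (doubled floor) and 0.438 (floor of 23.9 units). The cause of these changes was not tested. Leaving out an array leaves no residual degrees of freedom and so no test. No paired analysis was possible because the labels carry no replicate numbers.

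Of 24 list comparisons outside the central 95% of random lists, 12 stayed outside under all 7 alternatives, and of 60 inside, 50 stayed inside. The core clock median in sham was -0.065 over members Present on all 4 arrays, which leaves out genes such as Dbp that were not Present at ZT2, and in ADX it was 0.107. Both were 0.0 with the floor of 23.9 units. In ADX against sham at ZT2 the clock median, -0.106 and inside, was -0.258 with a floor of 1 unit and -0.338 over members Present on all 4 arrays, both outside. Averaging all probe sets of a gene gave 0.121 (sham) and 0.108 (ADX) for glucocorticoid targets, 0.112 for glucose synthesis in ADX, and -0.106 (sham), -0.043 (ZT2) and 0.106 (ZT14) for glycolysis and lipogenesis, all inside. The last list at ZT14 was 0.114 with a doubled floor or the floor of 23.9 units and 0.128 with members Present on all 4 arrays. With the floor of 23.9 units, the median was 0.0 for cell cycle genes at ZT2, -0.116 for endothelial markers in sham, and 0.2 (ADX day-night) and -0.094 (ZT2) for red cell markers. Beyond what is said of the clock list, the cause was not tested.

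Of 174 calls of 105 named genes, 168 stayed past 2-fold in the same direction under quantile normalization and 104 with the floor of 23.9 units, and none reversed. Of 22 readings from other probe sets of these genes, 12 passed 2-fold in the same direction, 9 had the same sign below 2-fold, and 1 probe set of Noct gave -0.244 in ADX against the reported 4.06.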

Other observations

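The remaining fixed lists lay inside the random range in all 4 comparisons as processed, though the growth hormone and the ribosomal list lay outside it in some under other settings (ribosomal proteins in ADX against sham at ZT2 over members Present on all 4 arrays, for example). Ribosomal protein genes (20 measured) had medians between -0.09 and 0.07, oxidative phosphorylation genes (32) between -0.07 and -0.01, and coagulation genes (17) between -0.12 and 0.06. Growth hormone and male-biased genes (22, among them the female-biased Cyp2b9 and Cyp2b13) lay between -0.11 and 0.03, with Igfbp3 2.37-fold and 2.17-fold higher at ZT14 in sham and ADX (in ADX log2 0.77, under 2-fold, with the floor at 23.9 units). Socs2, a growth hormone feedback gene of that list, was 2.61-fold lower at ZT14 in sham only past 2-fold, at a signal of 84.4 at ZT2 and 32.3 at ZT14. Bile acid genes (10) lay between -0.04 and 0.05, hepatocyte markers (13) between -0.04 and 0.00, and stellate cell markers (12) between 0.02 and 0.22. Bile duct, exocrine pancreas and skeletal muscle markers had 1, 3 and 2 measured members, too few to read.

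The glycolysis and lipogenesis list had a median of 0.15 (percentile 97.8) in ADX against sham at ZT14, and no member passed 2-fold. It lay inside the random range under 4 of 7 alternatives, with medians from 0.106 to 0.128. Within the glucose list, Slc7a2, a transporter of cationic amino acids, was 2.73-fold higher at ZT14 in ADX, and its signals were 140.0, 215.5, 105.0 and 286.9 in the order sham ZT2, sham ZT14, ADX ZT2 and ADX ZT14. Ass1 was 5.13-fold higher at ZT14 in ADX by a probe set with signals between 14.7 and 75.4. Higher in ADX at both times, and picked after their values were seen, were Cyp26a1, a retinoic acid hydroxylase, with log2 differences of 1.45 at ZT2 and 1.07 at ZT14, and Rnf145, with 1.04 and 1.63. The signal of the 3' actin control was 1619.9, 1611.2, 1732.6 and 1086.3 in the same order, lowest on the ADX ZT14 array.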
